A study of Rattus norvegicus with 9 samples.

How the data were processed

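Total RNA of prefrontal cortex from 9 male Lewis rats was hybridised to 1 Affymetrix rat expression array per rat, and per the labels' protocols the tissue was frontal cortex dissected without the olfactory bulb, taken 12 days after the last behavioural test. The deposited values are log2 expression per probe set, which the authors made with GCRMA in R 2.6.2, per the submitters' processing notes. GCRMA corrects background by probe sequence, normalizes between arrays and summarises the probes of a set. Its settings and the other steps of the authors' processing are not given in the sources used here, and scanner files were not analysed here. Of the probe sets tested, 47.0% had an identical value on at least 2 arrays.

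The table held 15923 probe sets. The 57 control probe sets were left out, and of the other 15866 the lowest 40% by mean over the 9 arrays were left out, at a mean log2 of 3.22, which kept 9520. Gene names came from the annotation of the array platform, and a rat RefSeq gene table gave only genomic gene lengths. The annotation gave 12783 probe sets 1 symbol, 312 several symbols and 2771 no listed gene. Of the probe sets tested, 7862 had 1 symbol and they covered 6793 genes. No probe set with several symbols was named. No coordinates are given. No other sample columns were in the table, and the highest correlation between 2 arrays was 0.996.

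The labels define 1 group and give each rat a value for startle, locomotion, plus maze and sugar feeding. For each measure, limma 3.58.1 in R 4.3.3 fitted a slope per SD of the measure over the 9 rats with lmFit and eBayes, leaving 7 residual degrees of freedom, with two-sided tests and Benjamini-Hochberg adjustment over the 9520 probe sets at 0.05. The spread is that between animals, and with 1 array each it also holds technical differences between arrays. Correlations across rats were tested two-sided over all 362880 pairings of the 9 rats, or 5040 for 7 rats, with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 in Python 3.11.15, and are called exact permutation tests. For Pearson r on untied values the smallest p these can give is 2.76e-06 for 9 rats and 0.000198 for 7 rats. It is higher for Spearman rho and with tied values. Each correlation was repeated without the 2 rats farthest from the median of the measure. Leaving out these extremes narrows the range of the measure, which by itself tends to weaken r. Figures were drawn with matplotlib 3.10.9.

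The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. For each measure the named genes are the 10 with a positive and the 10 with a negative slope of smallest limma p, whether or not they pass, with 1 probe set per gene, the one with the highest mean. Symbols that begin with LOC, RGD, MGC or AABR were not eligible. The 3 leading genes in each direction carry full statistics, and up to 4 members by smallest limma p are named for a gene list described with its members. Members of other lists, and genes that differ in rats 8 and 9, were chosen after their values were seen. There were 30 lists of pathways and cell type markers, including cell types that a dissection could bring along. A list's score in a rat is the mean of its genes' z scores, and its relation with each measure was tested over the pairings of rats, with adjustment over 26 lists and 4 measures. The 4 lists with fewer than 5 genes measured, for dopamine signalling, noradrenaline and acetylcholine receptors, choroid plexus and red blood cells, were not tested and held 4, 4, 3 and 3 genes. The limma camera test of the same lists, with a preset correlation of 0.01 and with an estimated one, was an alternative.

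Other alternatives were no filter, a filter at 70%, quantile normalization again, an intensity trend with robust moderation, ranks of the measure, the other 3 measures or the first principal component as covariates, array quality weights, 1 probe set per gene and leaving out each rat in turn. A term for the arrays of rats 8 and 9, the fit without these arrays, a principal component computed on the other 7 rats and the endothelial score as a covariate were chosen after seeing the data, the last with its bounds written before its own result. The limma fit was tested on simulated data in which 200 of 9520 probe sets received a known slope after the order of the rats was shuffled, 10 times per size and measure. Each measure was also put in 100 orders, the observed one included.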

Results

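Prefrontal cortex of 9 male Lewis rats, an inbred strain, was profiled with 1 Affymetrix rat expression array per rat. No treatment was applied and the rats form 1 group. Each rat carried 4 behavioural values, named startle, locomotion, plus maze and sugar feeding, so each comparison is a relation between expression and a behaviour across individuals of the same strain. The study's title places the question there: whether mRNA levels in the brain go with behaviour among inbred animals. The labels give no units for the 4 values, and the series design names only 3 tests, without the plus maze. Startle values ran from 67.7 to 501 with a mean of 276 ± 142 (SD, n = 9), and locomotion from 536 to 1102 with a mean of 772 ± 173 (SD, n = 9). Plus maze values ran from 0 to 18.7 with a mean of 6.68 ± 7.36 (SD, n = 9), and sugar feeding from 0.8 to 4.7 with a mean of 2.17 ± 1.19 (SD, n = 9). Median log2 expression over 15866 probe sets was 4.19, 4.11, 4.28, 4.17, 4.13, 4.22, 4.12, 4.21 and 4.15 for rats 1 to 9. The number of arrays limits the precision of every value that follows.

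None of the 6 pairs of behaviours was related at the threshold. Locomotion and sugar feeding gave the highest correlation, with r = 0.483 (exact permutation p = 0.187) and rho = 0.767 (exact permutation p = 0.0214, adjusted p = 0.128 over the 6 pairs). Without the 2 rats farthest from the median of locomotion, r was 0.702 (exact permutation p = 0.0812). Startle correlated with locomotion at r = -0.0916 (exact permutation p = 0.818) and rho = -0.25 (exact permutation p = 0.521), and with plus maze at r = 0.197 (exact permutation p = 0.617) and rho = 0.168 (exact permutation p = 0.666). With sugar feeding its r was -0.209 (exact permutation p = 0.60) and its rho -0.05 (exact permutation p = 0.912). Without the 2 rats farthest from the median of startle these r were -0.495, 0.660 and -0.305. Plus maze correlated with locomotion at r = 0.127 (exact permutation p = 0.754) and rho = 0.269 (exact permutation p = 0.480), and with sugar feeding at r = -0.317 (exact permutation p = 0.423) and rho = -0.101 (exact permutation p = 0.799). The first r was -0.188 without rats 1 and 3, the farthest from the median of locomotion. The second was 0.265 without rats 2 and 6, the farthest from the median of the plus maze. After Benjamini-Hochberg adjustment over the 6 pairs every r had an exact permutation p of 0.818.

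The arrays of rats 8 and 9 stood apart from the other 7 in the expression of many genes. Ryr2, the calcium release channel of the endoplasmic reticulum, averaged 2.33 log2 units higher in this pair and Gria1, an AMPA-type glutamate receptor subunit, 2.36. Kalrn, a guanine nucleotide exchange factor of dendritic spines, averaged 2.40 higher. Ebag9 differed by -1.80 and Commd10 by -1.32. Among 6793 genes, 1785 (26.3%) had both arrays beyond the range of the other 7 on the same side, with 447 higher and 1338 lower. Of these, 81 were higher and 51 lower by over 1 log2 unit. Chance gives 5.56% for a pair of arrays named in advance, but this pair was named from the same values, so the excess is no separate evidence. The first principal component, which held 49.6% of the variance, scored these arrays 35.6 and 30.2 and the other 7 between -12.1 and -1.62. The labels name no batch, so relations are given over all 9 rats and again over the other 7, a division chosen after the arrays had been compared.

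**Figure D1:**
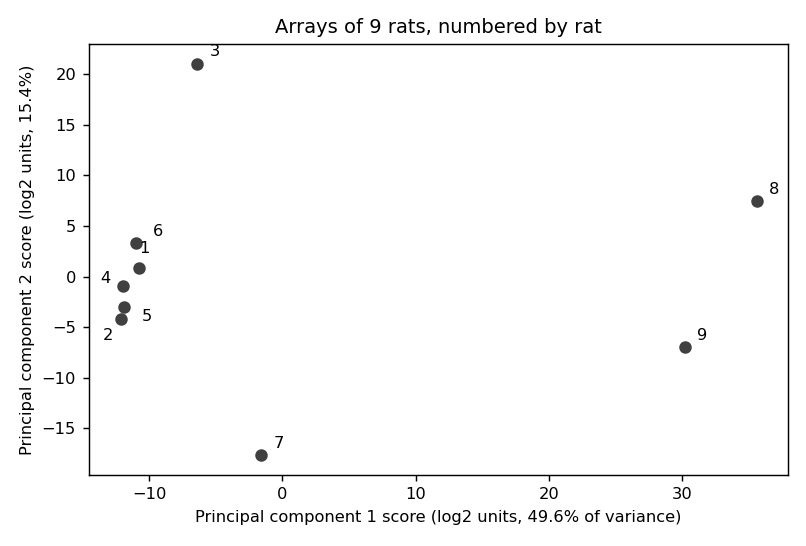
Scores of the 9 arrays, numbered by rat, on the first principal component (x axis, log2 units, 49.6% of variance) and the second (y axis, log2 units, 15.4%). Rats 8 and 9 lie at 35.6 and 30.2 on the x axis, and the other 7 lie between -12.1 and -1.62.

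The first principal component was not related to any of the 4 behaviours at the threshold. It correlated with startle at r = -0.533 (exact permutation p = 0.134, adjusted p = 0.535 over the 4 measures) and rho = -0.383 (exact permutation p = 0.313). Its r was 0.256 for locomotion, -0.356 for plus maze and 0.216 for sugar feeding, with adjusted exact permutation p = 0.601 for each. These values set 2 arrays against 7. Among the other 7 rats, r with startle was -0.118 (exact permutation p = 0.845), and the r with locomotion and with sugar feeding took the opposite sign, -0.450 and -0.303. Without the 2 rats farthest from the median of each measure, r was -0.591 for startle, 0.644 for locomotion, -0.103 for plus maze and 0.341 for sugar feeding.

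Over the 9 rats startle had the single-gene relations with the lowest adjusted p in limma, which did not hold without the 2 farthest rats or with array weights. Atf5, a transcription factor of the basic leucine zipper family, had a slope of -0.30 ± 0.033 log2 units per SD of startle (SE, n = 9), and its expression spanned 2.00-fold between the lowest and highest rat. Adgrb1, an adhesion G protein-coupled receptor of the brain, had a slope of -0.36 ± 0.048, and Mapre3, which binds growing microtubule ends, -0.30 ± 0.039. In the other direction Dhx36, a helicase that unwinds G-quadruplexes, had a slope of 0.62 ± 0.095 and a 4.14-fold span. A second Dhx36 probe set had a slope of 0.28 and a limma adjusted p of 0.0826. None of these genes passed an adjusted p of 0.05 in limma.

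The relation of Atf5 with startle had r = -0.975 (exact permutation p = 1.65e-05) and rho = -0.983 (exact permutation p = 3.31e-05), with a limma adjusted p of 0.0745. Its r was -0.924 without the 2 rats farthest from the median of startle and -0.975 in the 7 rats. Mapre3 had r = -0.954 (exact permutation p = 0.000171), rho = -0.950 (exact permutation p = 0.000353) and r = -0.871 without the 2 farthest rats. Its r in the 7 rats was -0.960. For Adgrb1, r was -0.945 (exact permutation p = 4.68e-05), rho -0.983 (exact permutation p = 4.96e-05), r without the 2 farthest rats -0.894 and r in the 7 rats -0.956. Mapre3 and Adgrb1 both had a limma adjusted p of 0.0826. Dhx36 had r = 0.912 (exact permutation p = 0.000821) and rho = 0.967 (exact permutation p = 0.000165), with r = 0.897 without the 2 farthest rats and 0.875 in the 7 rats. Dnajc24, a J-domain co-chaperone, had r = 0.905 (exact permutation p = 0.00106), rho = 0.783 (exact permutation p = 0.0172), r = 0.723 without the 2 farthest rats and 0.878 in the 7 rats. Id2, an inhibitor of basic helix-loop-helix factors, had r = 0.896 (exact permutation p = 0.00136), rho = 0.883 (exact permutation p = 0.00308), r = 0.850 without the 2 farthest rats and 0.898 in the 7 rats. The slope of Id2 was 0.25 ± 0.047, and a second Id2 probe set had a slope of 0.037.

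Syn1, the synaptic vesicle protein synapsin I, had a slope of -0.23 ± 0.039 and its second probe set -0.22. Scamp3, a secretory carrier membrane protein, had -0.37, Sik2, a salt-inducible kinase, -0.31, Kctd17 -0.21 and Dpf1, a subunit of neuronal chromatin remodelling complexes, -0.22. Supt6h, a transcription elongation factor, had -0.26 and Col4a2, a basement membrane collagen, -0.33. On the positive side Gosr1, a Golgi SNARE, had 0.27, although its second probe set had -0.028. Ostc, part of the oligosaccharyltransferase, had 0.18, Srprb, a subunit of the signal recognition particle receptor, 0.22 and Ghitm, a mitochondrial inner membrane protein, 0.18. Ccnc, cyclin C, had 0.18, Zfp347 0.29 and Gatad1 0.22. Of 9520 probe sets, 0 passed an adjusted p of 0.05 and 4 passed 0.1 in limma. At an unadjusted p under 0.01 there were 238, 122 positive and 116 negative, where 95.2 are expected by chance, and at 0.05 there were 1260. With a term for rats 8 and 9 the count at 0.01 was 195, and in the other 7 rats it was 377. Without rat 8 alone it was 382. Most slopes were then positive, 247 against 130 in the 7 rats and 293 against 89 without rat 8, as were 66 against 23 without the 2 farthest rats.

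**Figure D2:**
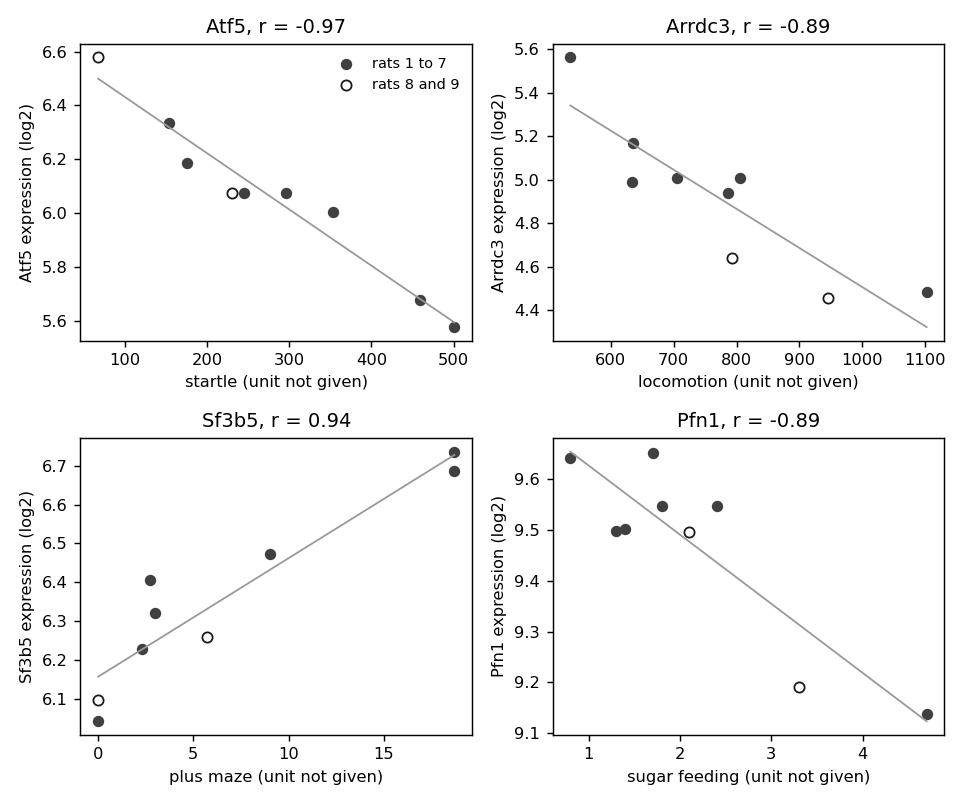
Log2 expression (y axes) against behavioural value (x axes, unit not given) for the gene with the largest slope relative to its error in each measure, with 1 point per rat, filled for rats 1 to 7 and open for rats 8 and 9, and a least-squares line. Atf5 has r = -0.975 with startle, Arrdc3 r = -0.887 with locomotion, Sf3b5 r = 0.935 with plus maze and Pfn1 r = -0.889 with sugar feeding.

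For locomotion the leading gene was Arrdc3, an arrestin-domain adaptor of receptor trafficking, with a slope of -0.31 ± 0.060 log2 units per SD (SE, n = 9) and a 2.15-fold span. Rnpep, an aminopeptidase, had a slope of -0.16 ± 0.037 and Il33, a cytokine released by damaged cells, -0.19 ± 0.048. The leading positive genes were Map4k1, a kinase of blood cells, at 0.36 ± 0.088, Tpsb2, a mast cell tryptase, at 0.17 ± 0.043 and Acer3, a ceramidase, at 0.29 ± 0.079. None passed an adjusted p of 0.05 in limma, and the lowest adjusted p was 1.00.

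The relation of Arrdc3 with locomotion had r = -0.887 (exact permutation p = 0.0018), rho = -0.800 (exact permutation p = 0.0138), r = -0.831 without the 2 rats farthest from the median of locomotion and r = -0.914 in the 7 rats. Rnpep had r = -0.889 (exact permutation p = 0.0020) and rho = -0.831 (exact permutation p = 0.0083), with -0.709 without the 2 farthest rats and -0.883 in the 7 rats. Il33 had r = -0.839 (exact permutation p = 0.0079) and rho = -0.567 (exact permutation p = 0.121), with -0.480 and -0.916 in the same subsets, and its second probe set had a slope of -0.030. Map4k1 had r = 0.815 (exact permutation p = 0.0139) and rho = 0.450 (exact permutation p = 0.230), with 0.686 and 0.852. For Tpsb2, r was 0.855 (exact permutation p = 0.00466) and rho 0.502 (exact permutation p = 0.172), with 0.783 and 0.848. Acer3 had r = 0.783 (exact permutation p = 0.016) and rho = 0.494 (exact permutation p = 0.180). Its r was 0.155 without the 2 farthest rats, so the relation did not hold in that narrower range, and 0.861 in the 7 rats.

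Further genes with negative locomotion slopes were Bhlhe41, a repressor of the circadian clock, at -0.17, Polg, the mitochondrial DNA polymerase, at -0.25, Scrib, a cell polarity scaffold, at -0.17 and Aprt, an enzyme of adenine salvage, at -0.18. Bri3 had -0.19, Pop4, a subunit of ribonuclease P, -0.13 and 4930522L14Rikl -0.24. Positive slopes were found for Hltf, a helicase-like factor, at 0.19, Pi4kb, a phosphatidylinositol kinase, at 0.20, Rbpms2 at 0.16, Bmt2 at 0.18, Pxk at 0.18, Pgap6 at 0.12 and Trappc8, part of a vesicle tethering complex, at 0.14. Without the 2 farthest rats r ran from 0.140 for Trappc8 to 0.867 for Pi4kb among these positive genes. Among the further negative genes it ran from -0.927 for 4930522L14Rikl to -0.281 for Bri3. In limma 0 of 9520 probe sets passed an adjusted p of 0.05, 27 had an unadjusted p under 0.01 and 187 under 0.05. The count at 0.01 was 56 with a term for rats 8 and 9, 83 in the other 7 rats, 49 without rat 8 and 171 without rat 1, the rat with the highest locomotion.

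For the plus maze, Sf3b5, a component of the splicing machinery, had a slope of 0.22 ± 0.038 log2 units per SD (SE, n = 9). Ifitm3 and Ifitm2, interferon-induced membrane proteins, had slopes of 0.32 ± 0.067 and 0.16 ± 0.036, and Fmod, the matrix proteoglycan fibromodulin, 0.38 ± 0.083. Fmod averaged 3.45 log2 units, near the lowest mean kept, 3.22. Id3, a relative of Id2, had 0.25 and Amotl2, an angiomotin family member, 0.25. None passed an adjusted p of 0.05 in limma, where the lowest was 0.999.

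The relation of Sf3b5 had r = 0.935 (exact permutation p = 0.000309), rho = 0.924 (exact permutation p = 0.00101), r = 0.802 without the 2 rats farthest from the median of the plus maze and 0.935 in the 7 rats. Rats 2 and 6 shared the highest plus maze value, 18.7, and several of the other relations were weaker without them. Ifitm3 had r = 0.861 (exact permutation p = 0.0176) and rho = 0.546 (exact permutation p = 0.133), with -0.136 without these rats and 0.880 in the 7 rats. Fmod had r = 0.847 (exact permutation p = 0.00811) and rho = 0.714 (exact permutation p = 0.0375), with 0.230 and 0.872 in the same subsets. Elfn2, a synaptic adhesion protein, had a slope of -0.22 ± 0.050, r = -0.859 (exact permutation p = 0.00569) and rho = -0.487 (exact permutation p = 0.186), with -0.537 and -0.872. The 4 other Elfn2 probe sets had slopes of -0.09 to 0.0046. Synj2, a phosphoinositide phosphatase, had r = -0.794 (exact permutation p = 0.00373) and rho = -0.698 (exact permutation p = 0.0439), with -0.450 and -0.824. For Cdk8, a kinase of the Mediator complex, r was -0.794 (exact permutation p = 0.0080) and rho -0.571 (exact permutation p = 0.114), with -0.291 and -0.819.

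Other positive plus maze slopes were 0.48 for Rbp4, a retinol carrier, 0.26 for Myl12a, a myosin light chain, 0.26 for Imp3 and 0.28 for C20h6orf89. Negative slopes were -0.36 for Limk1, a kinase that acts on cofilin, -0.14 for Meg3, an imprinted long noncoding RNA, -0.18 for Spata2 and -0.22 for Akap8l. They were -0.11 for Plekho1, -0.14 for Gne, an enzyme of sialic acid synthesis (0.11 without rats 2 and 6), and -0.21 for Cntfr, the receptor of ciliary neurotrophic factor. In limma 0 of 9520 probe sets passed an adjusted p of 0.05, 44 had an unadjusted p under 0.01, 38 of them positive, and 285 had one under 0.05. The count at 0.01 was 41 with a term for rats 8 and 9, 49 in the other 7 rats and 80 without rat 3.

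For sugar feeding, Pfn1, the actin-binding protein profilin 1, had a slope of -0.16 ± 0.038 log2 units per SD (SE, n = 9), and Stat3, a transcription factor of cytokine signalling, 0.15 ± 0.037. Irak1, a kinase of interleukin 1 receptor signalling, had -0.12 ± 0.032 and C1qtnf4 -0.16 ± 0.046. Rbl2, a member of the retinoblastoma family, had 0.21 ± 0.061 and Zkscan5, a zinc finger protein, 0.29 ± 0.085. A second Stat3 probe set had a slope of 0.26 ± 0.29. None passed an adjusted p of 0.05 in limma, and the lowest adjusted p was 1.00.

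The relation of Pfn1 had r = -0.889 (exact permutation p = 0.0039) and rho = -0.633 (exact permutation p = 0.076), with r = -0.330 without the 2 rats farthest from the median of sugar feeding and -0.893 in the 7 rats. Stat3 had r = 0.883 (exact permutation p = 0.00286) and rho = 0.683 (exact permutation p = 0.0503), with 0.40 and 0.896 in the same subsets. Irak1 had r = -0.898 (exact permutation p = 0.00272) and rho = -0.700 (exact permutation p = 0.0433), with -0.387 and -0.887. C1qtnf4 had r = -0.814 (exact permutation p = 0.00709) and rho = -0.767 (exact permutation p = 0.0214), with -0.544 and -0.854. For Rbl2, r was 0.786 (exact permutation p = 0.0168) and rho 0.569 (exact permutation p = 0.115), with 0.282 and 0.808. Zkscan5 had r = 0.770 (exact permutation p = 0.0304) and rho = 0.218 (exact permutation p = 0.572), with 0.175 and 0.826. The relations of Pfn1, Stat3, Irak1, Rbl2 and Zkscan5 were weaker without rats 4 and 8, the rats with the highest sugar feeding values, which were left out together.

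Other sugar feeding slopes were 0.13 for Hyou1, a chaperone of the endoplasmic reticulum, 0.12 for Adcy6, an adenylyl cyclase, 0.21 for Ak3, a mitochondrial adenylate kinase, and 0.16 for Epg5, a factor of autophagy. Arhgap18 had 0.20, Ethe1, an enzyme of sulfide oxidation, 0.17 and Cybc1 0.14. Without the 2 farthest rats Arhgap18 had -0.0022 and Cybc1 -0.0407, and Arhgap18 had -0.00820 without rat 4 alone. Negative slopes were -0.25 for Bola1, -0.15 for Pdk1, a kinase of pyruvate dehydrogenase whose second probe set had 0.026, and -0.11 for Mrpl23, a mitochondrial ribosomal protein. They were -0.20 for Rex1bd, -0.11 for Sbno1, -0.17 for Selenom and -0.10 for Rnf128. In limma 0 of 9520 probe sets passed an adjusted p of 0.05, 15 had an unadjusted p under 0.01 and 133 under 0.05. The count at 0.01 was 44 with a term for rats 8 and 9, 55 in the other 7 rats and 285 without rat 4, the rat with the highest sugar feeding. It was 30 without rat 8, 23 without rat 5 and 9 without rat 2.

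Among gene groups, microglial markers had the highest Pearson r with startle over the 9 rats, while by rho glutamate receptors and transporters lay farther from 0, at -0.833 (exact permutation p = 0.00827). The mean score of 12 microglia and macrophage markers had r = 0.733 (exact permutation p = 0.0204, adjusted p = 0.956) and rho = 0.767 (exact permutation p = 0.0214), and 11 of the 12 slopes were positive. Its r was 0.678 without the 2 farthest rats and 0.768 in the 7 rats. Lyz2, lysozyme, had a slope of 0.17 ± 0.040, P2ry12, the purinergic receptor of microglia, 0.32 ± 0.134, Csf1r, the receptor of colony-stimulating factor 1, 0.16 ± 0.072 and Tyrobp 0.11 ± 0.052. Serotonin signalling, with 6 genes, had r = 0.674 with startle (exact permutation p = 0.0443, adjusted p = 0.956), rho = 0.800 (exact permutation p = 0.0138), 0.362 without the 2 farthest rats and 0.894 in the 7 rats. Its receptor genes differed among themselves, with slopes of 0.19 for Htr2a, 0.056 for Htr1f and -0.18 for Htr5a. Htr2c had 0.19 over the 9 rats and -0.11 in the 7 rats, and Htr5a had 0.02 in the 7 rats. Htr1f and Htr5a averaged 3.55 and 3.62 log2 units, near the lowest mean kept, 3.22.

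Several vessel, immune and glial groups also had positive r with startle. It was 0.626 for 10 endothelial markers, all with positive slopes, 0.598 for pericyte and smooth muscle markers, 0.647 for interferon and antigen presentation, 0.522 for oligodendrocyte precursor markers and 0.389 for astrocyte markers. Without the 2 farthest rats these were 0.533, 0.491, 0.390, 0.403 and 0.288, and astrocyte markers had -0.0108 with the mean of all probe sets per gene. Oligodendrocyte and myelin markers, at -0.142, and meningeal and fibroblast markers, at -0.0267, did not share the sign. Rat 3, with the highest startle value, had the highest endothelial, interferon, oligodendrocyte precursor and astrocyte scores. Pericyte and smooth muscle scores were highest in rat 6, at 0.923, with rat 3 at 0.877. The positive relations of these groups with startle thus share a high value in rat 3 and may not be separate observations, which was not tested. Heat shock and unfolded protein response genes had r = 0.294 over the 9 rats and -0.119 in the 7 rats. The r with startle was -0.656 for 23 genes of synaptic vesicle release and -0.606 for 21 glutamate receptors and transporters. These were -0.330 and -0.662 without the 2 farthest rats and -0.807 and -0.377 in the 7 rats. Other neuronal groups differed in sign, such as GABA signalling with 0.215 over the 9 rats and -0.819 in the 7 rats, and opioid, cannabinoid and feeding peptides with 0.244 and -0.557. None of these groups passed adjustment.

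Meningeal and fibroblast markers had the highest Pearson r with the plus maze over the 9 rats, 0.682 (exact permutation p = 0.0456, adjusted p = 0.956), with rho = 0.655 (exact permutation p = 0.0624) and all 12 slopes positive. Without rats 2 and 6, which had the highest plus maze values, r was 0.126, and it was 0.706 in the 7 rats. Leaving out rats 2 and 6 narrows the range of the measure, so the lower r does not decide whether the relation rested on them. Fibrillar collagen Col3a1 had a slope of 0.86 ± 0.251, Col1a2 0.27 ± 0.088 and Gjb2, a gap junction protein, 0.29 ± 0.095, with -0.027 without rats 2 and 6. Col1a2 and Gjb2 averaged 3.52 and 3.30 log2 units, near the lowest mean kept, 3.22. Mitochondrial respiratory chain genes had r = 0.599 with the plus maze, with 41 of 49 slopes positive, and interneuron markers 0.313. Immediate early genes had -0.509, neurotrophins and CREB signalling -0.520 and olfactory bulb markers -0.275. Without rats 2 and 6 these 5 were 0.303, 0.210, -0.561, -0.406 and 0.0496. With locomotion, circadian clock genes had r = -0.498 over the 9 rats and -0.907 in the 7 rats, but 0.0544 without the 2 farthest rats and 0.0536 without rat 1 alone. GABA signalling had -0.409, upper-layer pyramidal neuron markers -0.354 and CRH and stress peptide signalling 0.351, and without the 2 farthest rats -0.704, -0.60 and 0.0905. With sugar feeding, striatal markers had r = 0.583, oligodendrocyte and myelin markers 0.535, glucocorticoid-responsive genes and receptors 0.534 and deep-layer pyramidal neuron markers 0.405. Without the 2 farthest rats these were 0.551, 0.0394, -0.210 and 0.136, so the myelin and glucocorticoid relations did not hold without those rats. Opioid, cannabinoid and feeding peptides had -0.365 and voltage-gated ion channels -0.265, and -0.544 and -0.272 without them.

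Each group is given with the measure of its largest r, and 4 of them also with startle. Of 30 groups, 26 had at least 5 measured genes, and 0 of the 104 relations passed adjustment, with a lowest adjusted exact permutation p of 0.956. At an unadjusted p under 0.05 there were 3, where 5.20 are expected by chance, and 9 in the 7 rats, where the lowest adjusted exact permutation p was 0.488. Adjusted over all probe sets, limma called 0 genes of any group. Adjusted over the list alone, it called 16 gene and measure pairs. There was no adjustment across the 104 relations, so some calls by chance are to be expected among them. For startle these were Ier5 and Klf10 of the immediate early genes, Dnm1 and Syn1 of synaptic vesicle release, Prkaca of neurotrophins and CREB signalling, Gsn of the myelin markers, Lyz2, Slco1a4 of the endothelial markers and Cux2 of the upper-layer markers. For the plus maze they were Col1a2, Col3a1, Fmod, Gjb2 and Igfbp2 of the meningeal markers, Ifitm3 of the interferon genes and Id3 of the astrocyte markers.

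**Figure D3:**
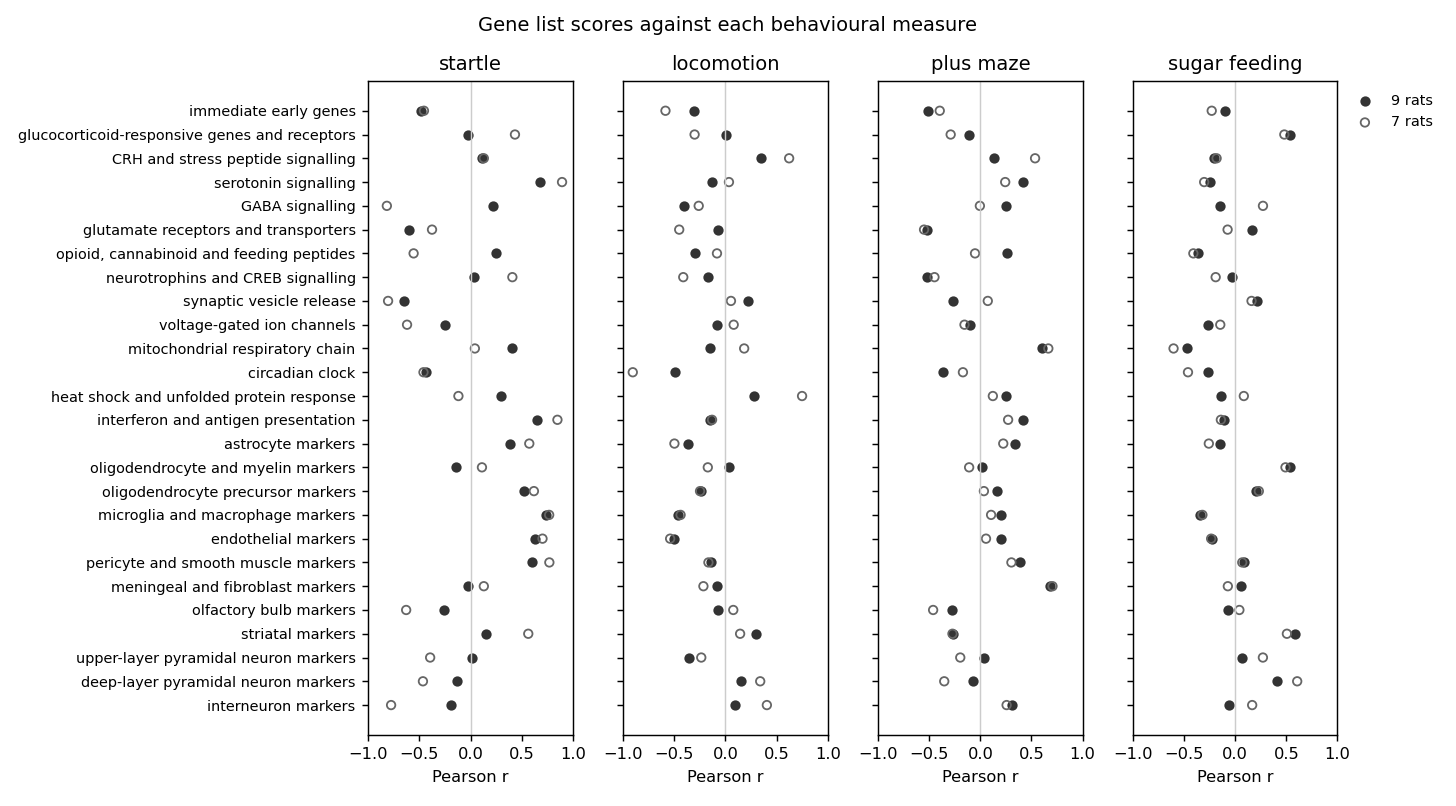
Pearson r (x axes) between the score of each of 26 gene lists (y axis) and each behavioural measure, filled for all 9 rats and open for the 7 rats without rats 8 and 9. The filled points for microglia and macrophage markers with startle and for meningeal and fibroblast markers with the plus maze lie at 0.733 and 0.682, and 0 of 104 relations passed adjustment.

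For each measure, some random pairings of the 9 rats with the behavioural values gave as many genes as the observed pairing. The 238 probe sets with an unadjusted p under 0.01 for startle were matched or exceeded by 9 of 100 orders of the startle values, the observed order included, and in the 7 rats the 377 were matched by 3 of 100. For locomotion 80 of 100 orders did so in the 9 rats, for the plus maze 52 and for sugar feeding 97. In simulated data with 200 changed probe sets, the fit recovered 80.5% of slopes of 0.5 log2 units per SD of startle and 18.5% of slopes of 0.25. The recovered shares at 0.5 were 82.0% for locomotion, 80.3% for the plus maze and 82.8% for sugar feeding.

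**Figure D4:**
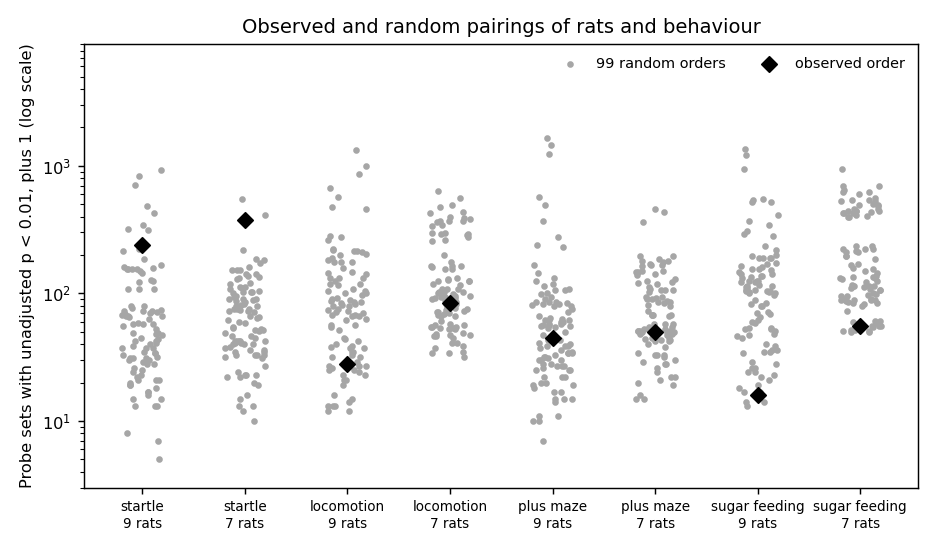
Probe sets with an unadjusted p under 0.01 (y axis, count plus 1, log scale) for the observed pairing of rats and behaviour (black diamonds) and 99 random pairings (grey points), per measure, in 9 rats and in the 7 rats without rats 8 and 9. The observed startle count is 238 in 9 rats and 377 in 7 rats, and random orders reach 928 and 552.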

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

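The tests of the 2 patterns weighed here were chosen after the patterns were seen, and only the bounds for the endothelial covariate were written before the result of the test itself. Of 123 sets of 9 values, made of measures, list scores and named genes, 13 held a rat whose gap to the nearest other rat was large against the whole range, where chance gives about 1 in 20, or 6.15. Many of them were genes named because they followed a measure in which the same rat was extreme.

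Rat 4, with the highest sugar feeding, stood apart in 6 genes named for that measure. The gap was 0.896 of the range for Arhgap18, 0.547 for Ak3, 0.529 for Zkscan5 and 0.588 for Ethe1, all highest in rat 4, and 0.612 for Mrpl23 and 0.622 for Rnf128, both lowest there. Rat 1, with the highest locomotion, stood apart in Pgap6 at 0.628 and Pxk at 0.528, both highest, and in Il33 at 0.591, lowest. Spata2 was lowest in rat 6 with a gap of 0.618, Htr5a highest in rat 8 with 0.919 and Tyrobp highest in rat 3 with 0.861. The score of voltage-gated ion channels was highest in rat 5 with a gap of 0.628.

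The arrays of rats 8 and 9 differed from the other 7 in 1785 of 6793 genes, and 2 conditions were set for labelled RNA that reached farther along the transcripts. The 5' minus 3' signal of the control transcripts averaged -1.64 and -1.40 log2 units in these rats and -2.21 to -1.85 in the others, which met the first but rested on beta-actin and hexokinase, whose signal was also higher in these rats, while GAPDH, at -0.463 and -0.775, lay within the range of the others. The second, a difference that grows with genomic gene length at a rho of 0.1 or more, was not met, with rho = 0.0385, so the explanation failed as it was set, although genomic length includes introns and is a weak measure of transcript length. Both rats were beyond the range of the others in 0 of 6 lists, for astrocytes, oligodendrocytes, microglia, endothelial cells, pericytes and meningeal cells. This argues against a shared shift beyond that range in the share of these cells. It cannot address a smaller shift or one in 1 rat. Rat 3 alone set the upper end for endothelial and microglial scores, at 1.69 and 1.49. The oligodendrocyte score was 0.713 in rat 8 and -0.571 in rat 9, against -0.566 to 0.484 in the others. Any 1 of the 4 behaviours is argued against too, with 0 of 4 and rat 9 within the range of the others in each. Both rats were also beyond that range in 0 of the other 6 cell type lists, but over the 9 rats their markers did not vary together beyond random lists. In the 7 rats interneuron, olfactory bulb and oligodendrocyte precursor markers did, at percentiles 99.6, 98.3 and 95.7 of random lists. The condition was set over the 9 rats, so these cell types and what separated the rats stay open.

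Startle had more probe sets with an unadjusted p under 0.01 than the other measures, 238 against 27 for locomotion, 44 for the plus maze and 15 for sugar feeding. This order turned without the 2 farthest rats, with 89 for startle and 195 for locomotion, with array weights, with 261 for startle and 404 for the plus maze, and without rat 4, with 191 for startle and 285 for sugar feeding. Chance cannot be excluded in the 9 rats, where 9 of 100 orders gave as many and the highest other gave 928, nor for locomotion (80 orders, highest other 1321), the plus maze (52, highest 1663) or sugar feeding (97, highest 1364). These highest orders correlated at 0.814 to 0.926 with the split between rats 8 and 9 and the rest, so they point to that structure of the samples. Without the arrays of rats 8 and 9 the startle count was 377, where 3 of 100 orders gave as many and the highest other gave 552. In these 7 rats 59 orders did so for locomotion (highest 633), 67 for the plus maze (highest 456) and 92 for sugar feeding (highest 938). This argues against the 2 arrays as needed for a high startle count, but the 3 of 100 was not adjusted over the measures. On the first component of all 9 rats, rat 7 lay nearest to rats 8 and 9, at -1.62. Rat 7 also had the lowest startle of the 7, so leaving out 2 arrays may not remove what set them apart. Whether the 238 probe sets are among the 377 was not tested, and 122 and 116 were positive and negative against 247 and 130. Rats 3 and 7, with the highest and lowest startle of the 7, lay apart on the first component of the 7 rats, at -20.6 and 19.8. With the endothelial score as a covariate the median slope kept 0.898 of its size, and 0.759 to 0.970 with each rat left out, which does not decide whether the share of blood vessel cells matters, and no other biological explanation was tested.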

How the results depend on the processing

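The term for rats 8 and 9 and the fits in the other 7 rats were chosen after the data were seen, and the cause of the changes listed here was not tested unless stated. There were 138 values, which hold each gene list only with the measure of its largest r, and 2554 alternatives. Of these, 2488 kept their direction and their side of the threshold or, for counts, moved by 1.5 times or less. No slope or correlation passed the threshold in its main fit, and most named genes were chosen for small p in the same rats. Keeping the side of the threshold was thus nearly fixed in advance, and the 2488 do not measure how robust the results are. Among the other alternatives, 28 changed sign, 36 counts, calls by camera included, moved by over 1.5 times and 2 single slopes passed the threshold anew. Those 2 were the Atf5 relation with startle, at a limma adjusted p of 0.0305 without a filter and 0.0470 with 1 probe set per gene, so the startle count was 1 in both. Over its alternatives the lowest limma adjusted p for startle was as high as 0.630, with the other 3 measures as covariates. Camera, which enters these totals only as a count of calls and not list by list, called 13 list relations with a preset correlation, and 0 with an estimated correlation, where the lowest adjusted p was 0.693. At an unadjusted p under 0.01, the startle count was 147 of 4760 probe sets with the filter at 70%, 102 with the other measures as covariates, 89 without the 2 farthest rats and 382 without rat 8. Locomotion gave 195 and sugar feeding 19 without the 2 farthest rats, 171 without rat 1 and 285 without rat 4, while plus maze gave 404 with array weights and 13 without the 2 farthest rats. Signs turned without the 2 farthest rats for locomotion and plus maze (-0.188), plus maze and sugar feeding (0.265), circadian clock genes with locomotion (0.0544), olfactory bulb markers with plus maze (0.0496) and glucocorticoid-responsive genes with sugar feeding (-0.210). The slopes so affected were Ifitm3 (-0.039), Gne (0.11) and Gjb2 (-0.027) with plus maze, and Arhgap18 (-0.0022) and Cybc1 (-0.0407) with sugar feeding. In the 7 rats the sign turned for the first principal component with locomotion (-0.450) and sugar feeding (-0.303), heat shock genes with startle (-0.119), Htr5a (0.020) and Htr2c (-0.11). Htr2c also turned with the first principal component as covariate (-0.079), array weights (-0.021) and the term for rats 8 and 9 (-0.051), and astrocyte markers with startle turned to -0.0108 with the mean of all probe sets. Leaving out each rat gave r from -0.717 to 0.307 for startle and locomotion (without rats 1 and 3, and 0.150 without rat 8), -0.0579 (rat 3) to 0.411 for locomotion and plus maze and -0.0604 (rat 8) to 0.689 for the first principal component and sugar feeding. It gave -0.731 to 0.0536 (rat 1) for circadian genes with locomotion and -0.408 to 0.0385 (rat 6) for olfactory bulb markers with plus maze. Slopes ran from -0.25 to 0.023 (rat 8) for Htr5a, -0.033 (rat 8) to 0.29 for Htr2c and -0.00820 (rat 4) to 0.24 for Arhgap18. The p-values rest on the spread between these 9 rats, which with 1 array each cannot be told apart from technical differences between arrays. No paired analysis was possible because the rats form 1 group with 1 array each.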

Other observations

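All tests in this part were chosen after the results were seen. Some gene groups varied together among the 9 rats without following a behaviour at the threshold. The 22 immediate early genes, which neurons switch on after activity, had a mean pairwise r of 0.399, against a median of 0.0538 over 10000 random lists matched on expression, and 0.395 in the 7 rats. Their score was highest in rats 7 and 9, at 1.01 in both. Fos spanned 5.09-fold between the lowest and highest rat, Junb 9.25-fold, Egr2 4.10-fold, Arc 4.01-fold and Nr4a1 4.64-fold. Fos, Egr1, Arc and Nr4a1 were highest in rat 7, and Junb, Dusp6 and Per1 in rat 9.

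Markers of vessels, microglia and the meninges also varied together. The mean pairwise r was 0.552 for 10 endothelial markers, 0.397 for 12 microglia and macrophage markers and 0.573 for 12 meningeal and fibroblast markers, and the medians of matched random lists were 0.0413, 0.0446 and 0.0567. In the 7 rats these values were 0.592, 0.465 and 0.628. Rat 3, with the highest startle value, had the highest endothelial and microglial scores, 1.69 and 1.49. Slco1a4, a transporter of the blood-brain barrier, measured 8.97 log2 units in rat 3, and C1qb, a complement component, 6.50. Meningeal scores were highest in rats 2 and 6, at 1.11 and 0.815. Igf2 spanned 10.2-fold and Ptgds, prostaglandin D synthase, 10.4-fold between the lowest and highest rat. Ptgds measured 12.2 log2 units in rat 2 and 8.80 in rat 5.

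In rats 8 and 9 the score of synaptic vesicle release was beyond the range of the other 7, at 0.301 and 0.711 against at most 0.158. Scores were below that range for GABA signalling, at -0.537 and -0.433, opioid, cannabinoid and feeding peptides, at -0.566 and -0.711, and mitochondrial respiratory chain genes, at -0.508 and -0.742. Heat shock genes scored -0.517 and -0.336, against at least -0.334 in the others. Among single genes 26.3% had both arrays beyond that range, so lying beyond it does not single out these lists. Of these lists only the respiratory chain genes varied together beyond random lists over the 9 rats, and they did not in the 7 rats.

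When the principal component analysis was made on the other 7 rats alone, its first component correlated with startle at r = -0.816 (exact permutation p = 0.00595, adjusted p = 0.0238 over the 4 measures) and rho = -0.857 (exact permutation p = 0.0238, adjusted p = 0.0952). Its scores ranged from -20.6 in rat 3, with the highest startle, to 19.8 in rat 7, with the lowest of the 7. Without rats 1 and 3, the 2 farthest from the median of startle, r was -0.708 (exact permutation p = 0.158). It was -0.673 (exact permutation p = 0.144) without rat 3 alone and -0.749 (exact permutation p = 0.0444) without rat 7 alone.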
